A study of Saccharomyces cerevisiae with 90 samples.

How the data were processed

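RNA levels of Saccharomyces cerevisiae were measured with Affymetrix arrays in 90 samples that fall into 29 groups by strain, nutrient composition, substrate and hours of growth. Per the labels, cells were quick-frozen in acid phenol, total RNA was cleaned with a Qiagen RNeasy kit, and labelled with biotin by Affymetrix IVT labelling. The values are log2 signals of 10928 probe sets as deposited, made with RMA according to the submitters' processing notes. The version of RMA and its settings are not given in the sources used here. The values ran from 3.42 to 15.6 log2, and the array medians from 6.76 to 7.23. The 75th percentile of an array lay between 10.7 and 10.9 and its 99th percentile between 14.87 and 14.97, so a gene near that level has little room to rise and its change may be larger than measured. The 6 arrays of wild-type on SD agar at 0 h carry fewer decimals than the others.

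In the platform annotation 7244 probe sets name 1 gene, of which 5498 are in the S. cerevisiae gene table and 1746 are not, the platform also carrying probes for another yeast. Another 3683 name none, 213 of them control or reporter probe sets. For 47 genes with several probe sets the brightest was used, which left 5449 genes to test. No gene with several probe sets had them called in opposite directions in wild-type SD agar against liquid. The probe sets of 118 tested genes carry a suffix for probes shared with other sequences. The background limit of an array was the 95th percentile of the probe sets for genes outside the S. cerevisiae table. It ranged from 5.72 to 6.33 (median 6.01), and 232 tested genes had a mean under that median. Where a gene was below background on all arrays of a group, its fold change is given as at least the fold over the background limit. Arrays give no count of molecules, so their number limits the precision, and the median standard deviation of a gene within groups was 0.156 log2.

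Groups were taken from the labels, and 47 comparisons were made: substrates within a strain and nutrient, strains within a substrate, nutrients within a substrate, 6 h with 0 h, and the difference of the agar effect between strains or nutrients. STE11-4 was set against pRS313 and MSB2* against pRS316. One linear model with a mean per group was fitted to all 90 arrays with limma 3.58.1 in R 4.3.3 (61 residual and 2.88 prior degrees of freedom). Its moderated test gave 2-sided p values, adjusted by Benjamini-Hochberg over the 5449 genes of each comparison. Genes were counted at an adjusted p under 0.05 and at least a 2-fold change. The smallest p of an exact permutation test with 3 arrays against 3 is 0.1, so single values have no exact test of their own. The labels do not state whether the replicates of a group are independent cultures, so p values measure the spread between these samples. Array titles of wild-type at 0 h, pRS313 and STE11-4 in SD liquid carry a b whose meaning is not given. These arrays and those with fewer decimals are whole groups, so neither set could be a block between agar and liquid or 6 h and 0 h. Of the 0 h agar arrays, A to C lay closer to each other (0.123 to 0.173 log2) than to D to F (0.212 to 0.331), and either set alone left the count of 6 h against 0 h within 1.5 times.

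The comparisons, the rule for named genes, 32 gene lists and the alternatives were written before the data were examined. The rule took, in wild-type substrate comparisons, the 10 largest rises and the 10 largest falls among genes with a standard name that passed the test and whose arrays did not overlap between groups, and 5 and 5 in every other comparison. It always took the pathway genes, FLO11, PGU1, HIS3 and URA3, and up to 4 members of a list described. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over lists. Of 1504 list tests, 489 passed at the preset correlation and 57 of these also with the estimated one, and results from lists state which. The analysis was tested on simulated data in which 200 genes were changed. At an adjusted p under 0.05 and at least 2-fold, it recovered in wild-type SD agar against liquid 51.5% of genes changed by 1 log2, 99.5% of those changed by 1.5 log2 and 100.0% at 2 log2, and for the difference of the agar effect between tec1 and wild-type 47.0%, 98.5% and 99.5%, with 0 to 2 false calls by limma. Without the fold threshold it recovered 98.0% and 88.0% at 1 log2, with 9 to 17 false calls.

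Alternatives were quantile normalization, centring each array on its median, leaving out genes in the dimmest 25% of means, the mean of a gene's probe sets, no fold threshold, a fit on the comparison's own arrays, replicate letters as a block, leaving out each array in turn, and, for msb2 and flo11, pRS316 as the control. The 0 h agar arrays were also used as replicates A to C or D to F. The control pRS313 for 15 comparisons was added after seeing the data, as were the heat shock list of 22 genes and the filamentation list without the gene altered in a strain. PGU1 means of 5.71 to 6.65 lie near background. Whether replicate letters pair cultures was checked by correlating the residuals of arrays with the same letter: for flo11 SD agar against liquid these were 0.13 to 0.30, above 0.1 for every letter, and in no other comparison did every letter pass. With the replicate block, flo11 SD agar against liquid gave 196 genes, against 195 without it. Arrays were called far from their group when their root mean square distance was over 2 times the median of 0.119 log2. For overlaps, independent lists would share the product of their sizes over the genes tested. In 100 draws, unchanged groups and a shared control were simulated from within-group spread, which leaves out a control that deviates as a whole.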

Results

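Budding yeast (Saccharomyces cerevisiae) was profiled on 90 Affymetrix arrays in 29 groups, each with 3 arrays except wild-type on SD agar at 0 h, which had 6. The design text states that cells from liquid cultures were set against cells from solid substrates, in wild-type and in strains altered in a proposed touch-sensing MAP-kinase pathway, to find the genomic response to touch. Substrates were liquid, agar and, for wild-type in SD, gelatin. The labels name the nutrient compositions SD, SLAD and SG. Strains were wild-type, Kss1K42R (a substitution in the MAP kinase KSS1), tec1, msb2 and flo11 mutants, the plasmids pRS313 and pRS316 without and with an allele (STE11-4 on pRS313, MSB2* on pRS316), and PGAL1-FLO11. All cultures were sampled at 6 h, except 2 wild-type groups in SD taken at 0 h. Signals are log2 values, and changes are given as log2 change ± SE from limma's fit over all arrays. Levels are given as mean ± SD with n = 3 arrays unless stated. A gene is said to have risen or fallen where its adjusted p was under 0.05. Counts of genes also require at least a 2-fold change.

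The targeted genes were read first, as a check of the labels. TEC1, a transcription factor of filamentous growth, read 5.67 ± 0.04 on agar and 5.30 ± 0.06 in liquid in the tec1 strain, not above background on any of these arrays, against 9.92 ± 0.02 and 10.04 ± 0.12 in wild-type. MSB2, a cell-surface mucin, read 4.99 ± 0.21 and 4.78 ± 0.63 in the msb2 strain, also not above background, against 12.65 ± 0.05 and 12.70 ± 0.09. FLO11, a cell-surface adhesin, read 6.77 ± 0.26 and 6.60 ± 0.60 in the flo11 strain and at least 10.01 in the mean of every other group. KSS1 carries a substitution in Kss1K42R, so its level checks nothing there. STE11 was higher in STE11-4 than with the empty plasmid, by 0.93 ± 0.07 on agar, and MSB2 was higher in MSB2* by 1.13 ± 0.19. HIS3 read 14.42 ± 0.02 with pRS313 on agar and 6.01 ± 0.20 in wild-type, and URA3 read 13.44 ± 0.17 with pRS316 and 4.70 ± 0.17 in wild-type. In SG, GAL1, the galactokinase gene, read 15.27 ± 0.04 on agar in wild-type, against 7.73 ± 0.14 in SD. In the arrays labelled PGAL1-FLO11, FLO11 did not follow GAL1: in SD, FLO11 read 14.50 ± 0.11 on agar and 10.64 ± 0.38 in liquid, close to wild-type, while GAL1 in SD liquid read 8.33 ± 0.32. These values go against FLO11 being driven by the GAL1 promoter in the SD samples. Whether the SD arrays hold the strain of their label is in doubt, and the label is used below without that being settled.

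**Figure D1:**
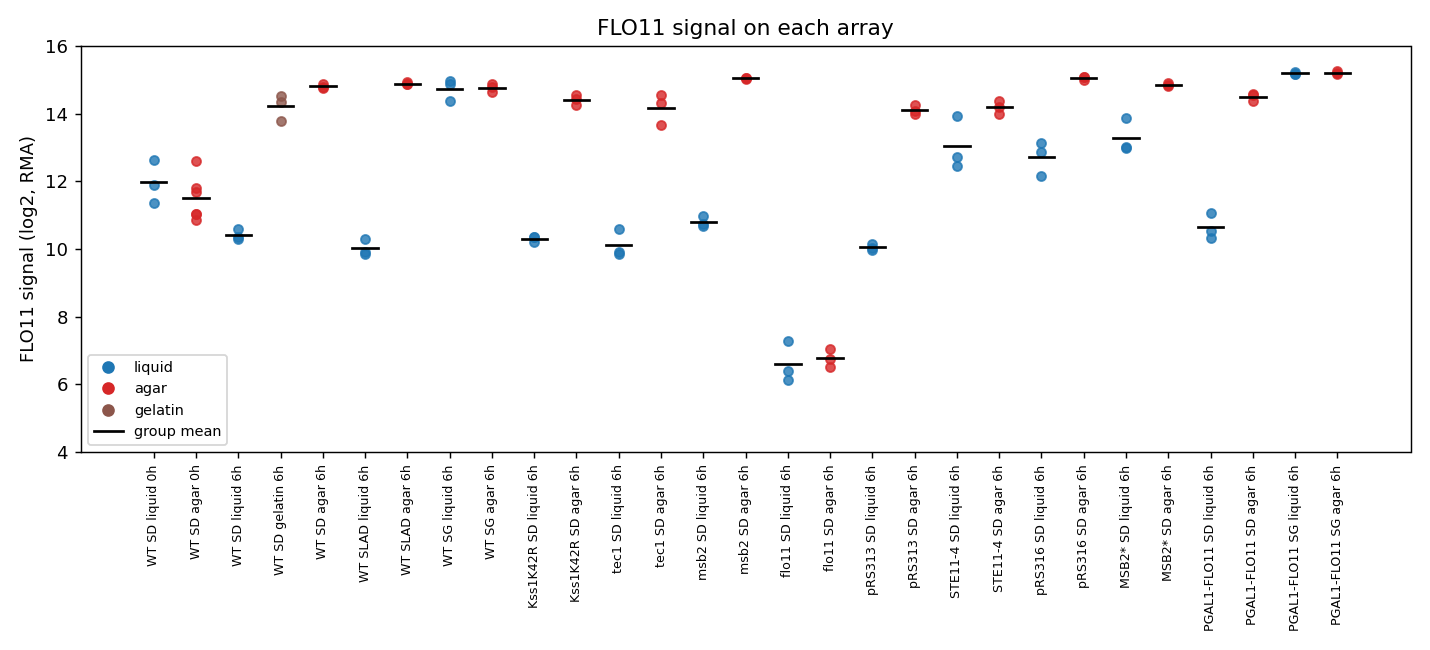
FLO11 signal (log2, RMA) on each array, by group on the x axis. Points are single arrays coloured by substrate and black lines are group means. In wild-type at 6 h the SD agar mean was 14.81, the SD gelatin mean 14.21 and the SD liquid mean 10.41, while in SG liquid it was 14.73.

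Growth of wild-type on SD agar instead of SD liquid asks how cells respond to a solid substrate. FLO11 showed the largest rise: it read 14.81 ± 0.06 on agar and 10.41 ± 0.16 in liquid (SD, n = 3 each), a 21.1-fold difference as measured (limma adjusted p = 7.72e-20), which may be too small since the agar value lies near the top of the array range. Among other large rises, the log2 change was 4.24 ± 0.34 for FMP23, 2.99 ± 0.20 for ZTA1, 2.60 ± 0.18 for BAT2, 2.47 ± 0.31 for SNO1 and 2.46 ± 0.18 for BDS1. BAT2 is the cytosolic branched-chain aminotransferase and SNO1 belongs to vitamin B6 synthesis. CIS1 rose at least 9.13-fold, BSC1 at least 3.75-fold and NDJ1 at least 3.28-fold, each being below background on all liquid arrays. The largest falls were -3.76 ± 0.54 for HSP30, -3.42 ± 0.22 for TOS8, -3.01 ± 0.27 for YPS3 and -2.98 ± 0.54 for YRO2. HSP30 encodes a plasma membrane heat shock protein and YPS3 a surface aspartic protease. In all, 94 genes rose and 153 fell at least 2-fold, while at any size 1678 rose and 1151 fell.

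Several of the gene lists moved mostly 1 way between SD agar and SD liquid. In cell wall and cell wall integrity genes, 18 of 22 measured fell and 4 did not pass (19 adjusted over the list alone), led by -2.46 ± 0.37 for PIR3, -2.39 ± 0.28 for CWP1 and -1.62 ± 0.21 for PST1. Ribosome biogenesis genes went the other way: 26 of 30 measured rose and 4 did not pass (29 adjusted over the list alone), at a median of 0.58. For cytosolic ribosomal protein genes, 62 of 127 measured rose, 4 fell and 61 did not pass (62 rose and 4 fell adjusted over the list alone), at a median of 0.09. General stress genes under Msn2 and Msn4 fell in part: 8 of 20 measured fell and 12 did not pass (8 adjusted over the list alone), with -1.95 ± 0.46 for HSP42 and -1.36 ± 0.35 for CTT1. Of iron uptake genes under Aft1, 12 of 19 measured fell and 7 did not pass (13 adjusted over the list alone), with -2.69 ± 0.47 for FIT2 and -2.31 ± 0.33 for ARN2. Zinc regulon genes fell in most cases (7 of 10 measured fell and 3 did not pass, 8 adjusted over the list alone). In nitrogen catabolite repression genes, 11 of 23 measured fell, 2 rose and 10 did not pass (12 fell and 2 rose adjusted over the list alone), with -2.70 ± 0.39 for DAL80 and -1.64 ± 0.29 for GAP1. In SD liquid this list was lower with pRS313 than in wild-type, by a median of -1.36, and on agar it rose with pRS316 and in msb2. Sulfur and methionine genes split: 13 of 21 measured fell, 4 rose and 4 did not pass (13 fell and 4 rose adjusted over the list alone), with -2.77 ± 0.30 for MUP1 and -1.58 ± 0.30 for STR3. For ergosterol synthesis, 13 of 19 measured fell, 2 rose and 4 did not pass (13 fell and 2 rose adjusted over the list alone), at a median of -0.19. None of these list shifts passed camera with an estimated correlation (adjusted p = 0.384 to 0.833).

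Of the pathway genes other than FLO11, STE12 changed by 0.50 ± 0.13, KSS1 by 0.48 ± 0.10, STE50 by 0.40 ± 0.13 and STE11 by -0.33 ± 0.07, while TEC1 and MSB2 did not pass at -0.12 ± 0.13 and -0.05 ± 0.19. Of the pathway components, 6 of 13 measured rose, 2 fell and 5 did not pass (6 rose and 2 fell adjusted over the list alone). Of the filamentation targets of Tec1, 3 of 10 measured rose, 1 fell and 6 did not pass (3 rose and 1 fell adjusted over the list alone), and of the pheromone-response genes, 5 of 20 measured fell, 3 rose and 12 did not pass (5 fell and 3 rose adjusted over the list alone). In the remaining lists, 4 FLO adhesins had 1 rise and 2 falls, 8 galactose genes had 1 rise and 1 fall, 23 Gcn4 amino acid synthesis genes had 7 rises and 7 falls, 16 low-oxygen genes had 3 rises and 5 falls, 33 respiratory chain genes had 7 rises and 14 falls and 18 gluconeogenesis and acetate genes had 1 rise and 5 falls. Likewise, 12 TCA cycle genes had 3 rises and 3 falls, 16 glycolysis genes had 6 falls, 9 hexose transporters had 1 rise and 2 falls, 15 phosphate genes had 4 rises and 6 falls, 17 G1/S genes had 3 rises and 1 fall and 11 G2/M genes had 1 rise. In the rest, 8 histone genes had 3 rises and 1 fall, 12 osmotic stress genes had 2 rises and 6 falls, 7 a-cell markers had 1 rise, 4 alpha-cell markers had 1 fall, 12 sporulation markers had 4 rises and 3 falls and 10 stationary-phase markers had 3 rises and 2 falls. The 3 measured plasmid and auxotrophy markers did not pass.

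Wild-type on SD gelatin was compared with SD liquid as another solid substrate. FLO11 read 14.21 ± 0.38 on gelatin, 13.9-fold above liquid (limma adjusted p = 1.30e-16). Other rises were 4.02 ± 0.34 for FMP23, 3.21 ± 0.31 for PTR2, 2.85 ± 0.46 for RFU1 and 2.79 ± 0.20 for ZTA1, PTR2 being the di- and tripeptide transporter. The falls included -3.94 ± 0.54 for HSP30, -3.76 ± 0.27 for YPS3, -3.44 ± 0.37 for PIR3 and -3.36 ± 0.54 for YRO2. Of cell wall genes, 16 of 22 measured fell and 6 did not pass (16 adjusted over the list alone), and of general stress genes, 12 of 20 measured fell and 8 did not pass (15 adjusted over the list alone). With an estimated correlation neither list passed camera (adjusted p = 0.389 to 0.873). In all, 77 genes rose and 135 fell at least 2-fold. Of these, 57 also rose and 83 also fell between agar and liquid, where independent lists would share 1.3 and 3.8. Across genes the changes correlated at 0.86 with a covariance of 0.207 (simulated unchanged groups 0.50 and 0.012, 0.0 genes shared). Both comparisons use the same 3 liquid arrays, too few to split, so part of the overlap may come from them. All 3 gelatin arrays lay far from their mean (A 0.596, B 0.334, C 0.297 log2 root mean square). B and C differed by 0.212, but from A by 0.919 and 0.880. Without A the comparison called 195 genes. With A, it called 88 fitted on its own groups and 9 with a replicate block.

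Directly against gelatin, PTR2 and the methionine permease genes MUP1 and MUP3 were lower in wild-type on SD agar. The log2 change was -3.05 ± 0.31 for PTR2, -2.36 ± 0.30 for MUP1, -1.77 ± 0.26 for MUP3 and -2.15 ± 0.22 for HPF1, HPF1 being a cell wall mannoprotein. Higher on agar were 2.69 ± 0.27 for PRM5, 2.39 ± 0.16 for PRM1, 2.27 ± 0.24 for CIS1 and 2.17 ± 0.25 for OSW2. FLO11 differed by 0.60 ± 0.29 (limma adjusted p = 0.179), with agar near the top of the array range. At least 2-fold, 27 genes were higher and 21 lower on agar, or 21 and 25 after quantile normalization. This comparison hung on 1 array: without gelatin replicate A, 131 genes passed. Fitted on the agar and gelatin arrays alone, limma called 0 genes, with 46 at least 2-fold at an unadjusted p under 0.05.

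**Figure D2:**
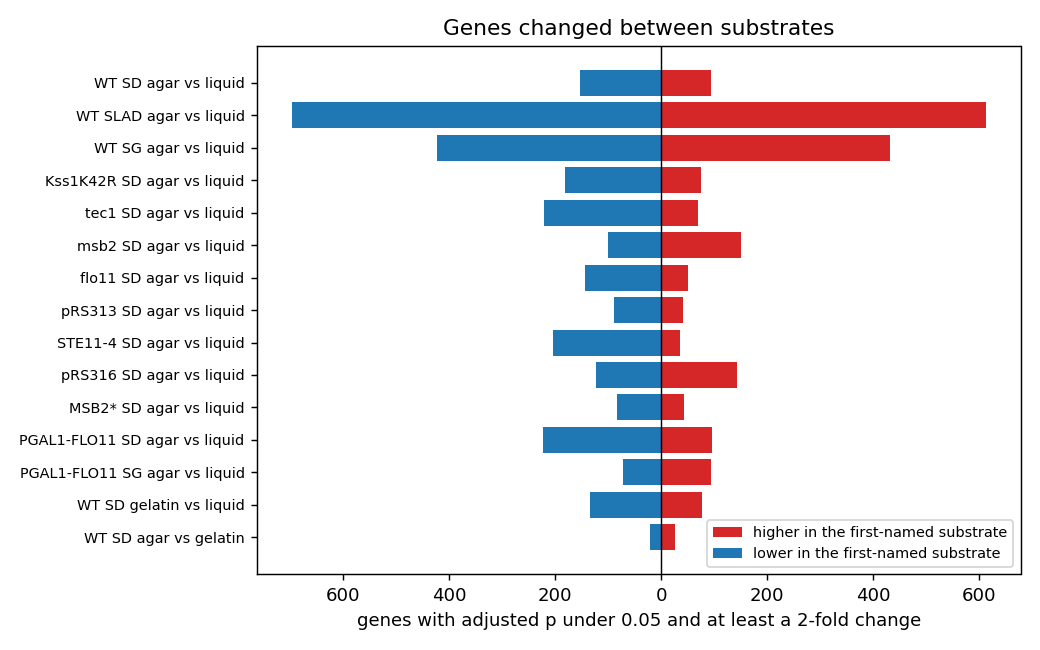
Number of genes at least 2-fold higher (right, red) or lower (left, blue) on the first-named substrate at an adjusted p under 0.05, one bar pair per comparison; the x axis counts genes. The SLAD bars reach 613 and 697 genes and the bars of agar against gelatin 27 and 21.

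In SLAD, wild-type had higher sulfur genes and lower general stress genes on agar than in liquid. The log2 changes were 4.93 ± 0.10 for MET3, 4.16 ± 0.19 for SUL1 and 4.36 ± 0.19 for SUL2, MET3 encoding ATP sulfurylase and SUL1 and SUL2 sulfate permeases. FLO11 read 14.88 ± 0.04 on agar and 10.01 ± 0.24 in liquid. Of sulfur and methionine genes, 21 of 21 measured rose (21 adjusted over the list alone), at a median of 2.76, and this list passed camera with an estimated correlation (adjusted p = 0.030). The falls included -6.57 ± 0.40 for GPH1, -6.30 ± 0.23 for HXT5 and -5.96 ± 0.18 for DUR3, GPH1 being glycogen phosphorylase and DUR3 the urea transporter. In general stress genes, 19 of 20 measured fell and 1 did not pass (19 adjusted over the list alone), at a median of -2.82, and in gluconeogenesis, glyoxylate and acetate genes, 16 of 18 measured fell, 1 rose and 1 did not pass (16 fell and 1 rose adjusted over the list alone). Of G2/M genes, 11 of 11 measured rose (11 adjusted over the list alone). Cytosolic ribosomal protein genes moved by a median of 0.41 (117 of 127 measured rose, 2 fell and 8 did not pass, 117 rose and 2 fell adjusted over the list alone). These last 4 lists did not pass camera with an estimated correlation (adjusted p = 0.138 to 0.378). Counts were 613 up and 697 down. The agar effect differed from that in SD for 955 genes, 408 with a higher and 547 with a lower change, led by 5.46 ± 0.27 for SUL2, 5.43 ± 0.43 for MUP1 and 5.07 ± 0.19 for MHT1, and on the lower side by -6.43 ± 0.48 for FMP16 and -5.97 ± 0.39 for ISF1. Of sulfur genes in that difference, 21 of 21 measured rose (21 adjusted over the list alone), adjusted p = 5.10e-04 with an estimated correlation.

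On agar, SLAD and SD cultures of wild-type were close, with 20 genes higher and 4 lower in SLAD. The higher genes were led by 2.42 ± 0.39 for DAL80, 2.18 ± 0.35 for DAL7 and 1.68 ± 0.30 for MUP1. DAL80 and DAL7 belong to nitrogen catabolite repression, of which 6 of 23 measured rose, 3 fell and 14 did not pass (9 rose and 4 fell adjusted over the list alone). In liquid the nutrients differed by 516 genes higher and 394 lower in SLAD, or 436 and 463 after quantile normalization and 450 and 481 after median centring. Sulfur genes were lower: 21 of 21 measured fell (21 adjusted over the list alone), with -4.72 ± 0.19 for SUL2, -4.61 ± 0.10 for MET3 and -3.75 ± 0.30 for MUP1 (camera adjusted p = 0.0058 with an estimated correlation). Higher in SLAD liquid were 6.60 ± 0.24 for SPG4 and 6.10 ± 0.32 for GPM2. In general stress genes, 18 of 20 measured rose and 2 did not pass (18 adjusted over the list alone). The stress list missed the threshold with an estimated correlation (adjusted p = 0.421), as did nitrogen catabolite repression on agar (adjusted p = 0.949).

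In SG, FLO11 read 14.73 ± 0.32 in liquid and 14.76 ± 0.12 on agar, both near the top of the array range, so that a rise could not be judged. Rises on agar were 3.73 ± 0.15 for SFG1, 3.28 ± 0.18 for BDS1 and 2.66 ± 0.19 for PGU1, SFG1 being a regulator of surface growth and PGU1 the secreted polygalacturonase. Of filamentation targets, 8 of 10 measured rose, 1 fell and 1 did not pass (8 rose and 1 fell adjusted over the list alone), with 2.66 ± 0.19 for PGU1, 1.28 ± 0.19 for MSB2 and 1.17 ± 0.10 for KSS1. Falls were -5.46 ± 0.31 for TKL2, -5.39 ± 0.54 for YRO2 and -4.62 ± 0.40 for GPH1, TKL2 being a transketolase. General stress genes fell as a group (19 of 20 measured fell and 1 did not pass, 19 adjusted over the list alone). In ribosome biogenesis, 30 of 30 measured rose (30 adjusted over the list alone), at a median of 1.42. Of cytosolic ribosomal protein genes, 125 of 127 measured rose and 2 did not pass (125 adjusted over the list alone), at a median of 0.53, which passed camera with an estimated correlation (adjusted p = 0.0338). The other 3 lists did not (adjusted p = 0.39). In all, 433 genes rose and 424 fell. The wild-type SG liquid arrays may stand apart. Between the arrays labelled PGAL1-FLO11 and wild-type in SG liquid, the stress median was -2.45 and that of ribosome biogenesis 1.68. For agar against liquid in wild-type these medians were -2.52 and 1.42. Replicate C of wild-type SG liquid lay 0.313 log2 from its group. The agar effect differed from that in SD for 682 genes, with 3.62 ± 0.38 for YPS3 and 3.34 ± 0.39 for CWP1 on the higher side and -5.12 ± 0.48 for FMP16 and -5.10 ± 0.31 for RTN2 on the lower. Of general stress genes in this difference, 16 of 20 measured fell and 4 did not pass (16 adjusted over the list alone), and of ribosome biogenesis genes, 22 of 30 measured rose and 8 did not pass (22 adjusted over the list alone), adjusted p = 0.409 to 0.65 with an estimated correlation.

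Wild-type in SG had higher galactose genes and lower HXT1 and HXT3 than in SD. On agar, the log2 change was 9.17 ± 0.28 for GAL10, 7.78 ± 0.18 for GAL2 and 7.54 ± 0.25 for GAL1, and GAL7 was at least 424-fold higher. GAL1 lay at the top of the array range, so its change may be larger. HXT1 and HXT3 are low-affinity hexose transporters, and their changes were -8.44 ± 0.33 for HXT1 and -4.35 ± 0.14 for HXT3. Of galactose regulon genes, 8 of 8 measured rose (8 adjusted over the list alone), and of respiratory chain and ATP synthase genes, 33 of 33 measured rose (33 adjusted over the list alone), at a median of 0.59. Of gluconeogenesis, glyoxylate and acetate genes, 17 of 18 measured rose and 1 did not pass (17 adjusted over the list alone), and of TCA cycle genes, 12 of 12 measured rose (12 adjusted over the list alone). In filamentation targets, 8 of 10 measured rose and 2 did not pass (8 adjusted over the list alone), with 2.92 ± 0.25 for DDR48, 2.39 ± 0.19 for PGU1 and 2.24 ± 0.12 for SVS1, and in ergosterol synthesis, 15 of 19 measured fell, 1 rose and 3 did not pass (15 fell and 1 rose adjusted over the list alone). These 6 lists passed camera with an estimated correlation (adjusted p = 8.75e-05 to 0.0302). On agar 465 genes were higher and 206 lower in SG, or 355 and 304 after quantile normalization.

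In liquid, 934 genes were higher and 672 lower in SG than in SD, or 698 and 876 after quantile normalization and 733 and 872 after median centring. The galactose genes rose again (8 of 8 measured rose, 8 adjusted over the list alone), with 8.11 ± 0.18 for GAL2 and 6.99 ± 0.25 for GAL1 and a camera adjusted p of 0.0102 with an estimated correlation. General stress genes were higher in SG liquid, where 20 of 20 measured rose (20 adjusted over the list alone), at a median of 3.92. Ribosome biogenesis genes were lower (30 of 30 measured fell, 30 adjusted over the list alone), at a median of -1.40. Of cytosolic ribosomal protein genes, 121 of 127 measured fell, 1 rose and 5 did not pass (121 fell and 1 rose adjusted over the list alone), with an adjusted p of 0.0424 under an estimated correlation, where the stress and ribosome biogenesis lists did not pass (adjusted p = 0.215 to 0.359). Since these lists also set wild-type SG liquid apart from PGAL1-FLO11 SG liquid (medians above), how much of these shifts goes with the nutrient was not determined. Among the falls in liquid was -7.94 ± 0.33 for HXT1.

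The Kss1K42R and tec1 strains test the kinase and the transcription factor of the pathway. Both still raised FLO11 on SD agar, to 14.41 ± 0.16 in Kss1K42R and 14.18 ± 0.45 in tec1, from 10.30 ± 0.08 and 10.11 ± 0.41 in liquid. In Kss1K42R, other rises were 3.81 ± 0.34 for FMP23, 3.11 ± 0.24 for CIS1 and 3.08 ± 0.20 for ZTA1, and falls were -5.84 ± 0.54 for HSP30, -5.69 ± 0.54 for YRO2, -4.38 ± 0.27 for ZRT1 and -4.38 ± 0.29 for AQY2, ZRT1 being the high-affinity zinc transporter and AQY2 an aquaporin. In tec1 the rises were 3.46 ± 0.24 for CIS1, 3.36 ± 0.34 for FMP23 and 3.08 ± 0.18 for BDS1, and the falls -6.08 ± 0.54 for YRO2, -5.09 ± 0.54 for HSP30 and -4.42 ± 0.29 for AQY2. Of cell wall genes, 19 of 22 measured fell and 3 did not pass (19 adjusted over the list alone) in Kss1K42R, and 16 of 22 measured fell and 6 did not pass (17 adjusted over the list alone) in tec1. In general stress genes, 10 of 20 measured fell and 10 did not pass (10 adjusted over the list alone) in Kss1K42R, and 14 of 20 measured fell and 6 did not pass (14 adjusted over the list alone) in tec1. These lists did not pass camera with an estimated correlation (adjusted p = 0.595 to 0.767 and 0.756). The counts were 75 genes up and 182 down in Kss1K42R, and 70 up and 222 down in tec1. Of the 247 genes of the wild-type SD agar response, 202 passed in the same direction in Kss1K42R and 200 in tec1.

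On agar, both strains had lower messages than wild-type of a small set of genes that includes filamentation targets. In Kss1K42R, the log2 differences were -1.76 ± 0.29 for FMP45, -1.60 ± 0.37 for PIR3 and -1.59 ± 0.27 for PRM5. In tec1, they were -2.12 ± 0.15 for SRD1, -2.04 ± 0.30 for PUF3 and -1.83 ± 0.27 for PRM5, while TEC1 was at least 13.1-fold lower. NDJ1 was at least 3.35-fold lower in Kss1K42R and at least 3.09-fold lower in tec1. Of filamentation targets, 4 of 10 measured fell and 6 did not pass (6 adjusted over the list alone) in Kss1K42R, with -1.17 ± 0.25 for DDR48 and -0.86 ± 0.19 for MSB2, and 4 of 10 measured fell and 6 did not pass (5 adjusted over the list alone) in tec1, which passed camera with an estimated correlation (adjusted p = 2.56e-04, and 0.0863 in Kss1K42R). Without TEC1 itself, 3 of 9 fell in tec1, adjusted p = 0.0456, and without KSS1, 3 of 9 in Kss1K42R, adjusted p = 0.216. At least 2-fold, 3 genes were higher and 27 lower in Kss1K42R, and 2 higher and 34 lower in tec1. Against pRS313 there were 22 higher and 31 lower in Kss1K42R, with 7 shared with the list against wild-type, and 23 higher and 46 lower in tec1, with 13 shared. The lists of both strains against wild-type shared 2 and 23 genes, against 0.0 and 0.2 for independent lists. The changes correlated at 0.87 across genes with a covariance of 0.054 (simulated unchanged groups 0.50 and 0.012, 0.0 genes shared). Part of the overlap may come from the 3 shared wild-type arrays, too few to split.

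In SD liquid, the same strains had lower DAL80, DAL7 and DAL5 than wild-type, genes under nitrogen catabolite repression. The log2 differences were -3.36 ± 0.39 for DAL80, -2.97 ± 0.35 for DAL7 and -2.96 ± 0.45 for DAL5 in Kss1K42R, and -3.16 ± 0.39 for DAL80, -2.61 ± 0.35 for DAL7 and -2.23 ± 0.45 for DAL5 in tec1. Of nitrogen catabolite repression genes, 17 of 23 measured fell, 2 rose and 4 did not pass (18 fell and 2 rose adjusted over the list alone) in Kss1K42R, and 17 of 23 measured fell, 2 rose and 4 did not pass (18 fell and 2 rose adjusted over the list alone) in tec1, without passing camera under an estimated correlation (adjusted p = 0.0627 and 0.194). This shift was also present between the pRS313 and pRS316 strains and wild-type in SD liquid, with medians of -1.36 and -1.22. Against pRS313 in place of wild-type, a choice made after the data had been seen, the list's median was 0.40 in Kss1K42R and 0.48 in tec1. Higher in the mutants were 3.49 ± 0.51 for ADA2, 2.99 ± 0.27 for ZRT1 and 2.85 ± 0.32 for GPM2 in Kss1K42R and 3.61 ± 0.32 for GPM2 and 2.76 ± 0.54 for YRO2 in tec1. Kss1K42R had 43 genes higher and 30 lower, or 26 and 38 after quantile normalization. In tec1 the counts were 53 and 29, or 34 and 32. The lists shared 33 and 25 genes, with 0.4 and 0.2 for independent lists. Across genes the correlation was 0.93 and the covariance 0.111 (simulated unchanged groups 0.50 and 0.012, 0.0 genes shared). Part of the overlap may come from the shared wild-type arrays. The agar effect itself differed from wild-type for 71 genes in Kss1K42R, 22 higher and 49 lower (23 and 27 after quantile normalization), with 3.38 ± 0.56 for DAL80, 2.97 ± 0.64 for DAL5 and -2.98 ± 0.38 for ZRT1. In tec1 it differed for 107 genes, 18 higher and 89 lower (21 and 46 after quantile normalization), with 3.27 ± 0.56 for DAL80, -3.10 ± 0.76 for YRO2 and -3.08 ± 0.46 for GPM2.

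The flo11 strain asks how much of the agar response needs the adhesin. Rises on agar in this strain were 3.10 ± 0.18 for BDS1, 3.01 ± 0.24 for YCT1 and 2.84 ± 0.24 for CIS1, BDS1 being a sulfatase and YCT1 a cysteine transporter. Falls were -3.65 ± 0.47 for TMA10, -3.31 ± 0.54 for HSP30 and -3.30 ± 0.27 for YPS3. Of cell wall genes, 15 of 22 measured fell and 7 did not pass (16 fell and 1 rose adjusted over the list alone). Their camera adjusted p with an estimated correlation was 0.795. Counts were 51 up and 144 down, and 163 of the 247 wild-type response genes passed the same way (pRS313 138, pRS316 141). On agar, 5 genes were higher and 14 lower in flo11 than in wild-type, the latter with FLO11 itself, -1.92 ± 0.37 for DDR2, -1.88 ± 0.34 for RTC3 and -1.79 ± 0.16 for PRM1. Against pRS316 there were 36 higher and 220 lower (11 shared), and against pRS313 18 higher and 32 lower (3 shared). Against pRS316, PRM1 differed by 0.14. In liquid, flo11 had lower DAL genes, with -3.50 ± 0.39 for DAL80 and -3.46 ± 0.45 for DAL5. Of nitrogen catabolite repression genes, 18 of 23 measured fell, 1 rose and 4 did not pass (18 fell and 1 rose adjusted over the list alone), adjusted p = 0.149 with an estimated correlation, and against pRS313 their median was 0.13. Liquid counts were 51 higher and 40 lower, or 27 and 71 after quantile normalization and 31 and 61 after median centring, as the median over all genes was 0.145. Without flo11 liquid replicate B, 154 genes passed. The agar effect differed from wild-type for 103 genes, 42 higher and 61 lower (66 and 25 after quantile normalization, 80 and 32 after centring, with an all-gene median of -0.138). This number was 198 without flo11 liquid replicate B and 55 without replicate C. It was led by -4.23 ± 0.41 for FLO11, 3.32 ± 0.56 for DAL80 and 3.31 ± 0.64 for DAL5, DAL80 reading -0.63 against pRS316, and of nitrogen catabolite repression genes, 16 of 23 measured rose and 7 did not pass (18 adjusted over the list alone), adjusted p = 0.191 with an estimated correlation.

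The msb2 strain tests the mucin MSB2. FLO11 rose on SD agar to 15.05 ± 0.02 from 10.79 ± 0.17 in liquid. Other large rises were 4.28 ± 0.34 for BTN2 and 4.00 ± 0.46 for HSP42, HSP42 being a small heat shock protein. Falls included -3.51 ± 0.30 for MUP1, -3.28 ± 0.15 for MIG3, -3.15 ± 0.33 for HXT1 and -2.90 ± 0.31 for MIG2, MIG2 and MIG3 being glucose repressors. General stress genes rose here (14 of 20 measured rose and 6 did not pass, 14 adjusted over the list alone), as did nitrogen catabolite repression genes (18 of 23 measured rose, 1 fell and 4 did not pass, 18 rose and 1 fell adjusted over the list alone). Of respiratory chain and ATP synthase genes, 25 of 33 measured rose and 8 did not pass (26 adjusted over the list alone), at a median of 0.32, which passed camera with an estimated correlation (adjusted p = 0.0346), unlike the stress and nitrogen lists (adjusted p = 0.263 to 0.634). Counts were 151 up and 100 down. Of the 247 wild-type response genes, 147 passed the same way (pRS313 138, pRS316 141) and 19 the opposite.

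Against wild-type on agar, msb2 had higher messages of the chaperones HSP42, HSP78 and HSP82. The log2 differences were 4.38 ± 0.46 for HSP42, 4.11 ± 0.34 for BTN2, 3.41 ± 0.29 for HSP78 and 3.22 ± 0.26 for HSP82, and -3.05 ± 0.33 for HXT1 and -2.76 ± 0.15 for MIG3. Against pRS316 in place of wild-type these turned for HSP42 (-0.49), BTN2 (-0.31) and HXT1 (2.24). In general stress genes, 14 of 20 measured rose, 1 fell and 5 did not pass (14 rose and 1 fell adjusted over the list alone), adjusted p = 0.693 with an estimated correlation, and their median against pRS316 was -0.62. Of 22 heat shock genes, a list chosen after the data had been seen, 21 were higher in msb2 (median 1.39), 19 in the control strain pRS316 (median 1.23) and 19 in MSB2* (median 1.06). On agar, 100 genes were higher and 63 lower in msb2, or 66 and 77 after quantile normalization. Against pRS316 there were 19 higher and 79 lower, with 11 shared. Fitted on these 2 groups alone the number was 93. It was 276 without msb2 agar replicate A and 101 without replicate C, which lay 0.276 and 0.279 log2 from their group. In liquid, lower genes were -3.72 ± 0.39 for DAL80, -3.43 ± 0.45 for DAL5 and -3.11 ± 0.35 for DAL7. Of nitrogen catabolite repression genes, 18 of 23 measured fell and 5 did not pass (19 adjusted over the list alone), with a camera adjusted p of 0.016 under an estimated correlation and a median of 0.16 against pRS313. Liquid counts were 19 higher and 64 lower, or 1086 and 420 without a fold threshold, with an all-gene median of 0.115. The agar effect differed for 296 genes, 153 higher and 143 lower, with 5.95 ± 0.65 for HSP42, 4.81 ± 0.49 for BTN2 and 4.53 ± 0.56 for DAL80, and on the lower side -3.01 ± 0.46 for HXT1 and -2.52 ± 0.21 for MIG3. BTN2 read -0.08 against pRS316. The number was 450 without msb2 agar replicate A and 193 without replicate C. In that difference 18 of 23 nitrogen catabolite repression genes rose and 5 did not pass (19 adjusted over the list alone). Of respiratory genes 25 of 33 rose and 8 did not pass (27). Both lists passed camera with an estimated correlation (adjusted p = 0.0334 and 0.0053). The nitrogen list also rose on agar with pRS316, by a median of 0.81 (1.01 in msb2).

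**Figure D3:**
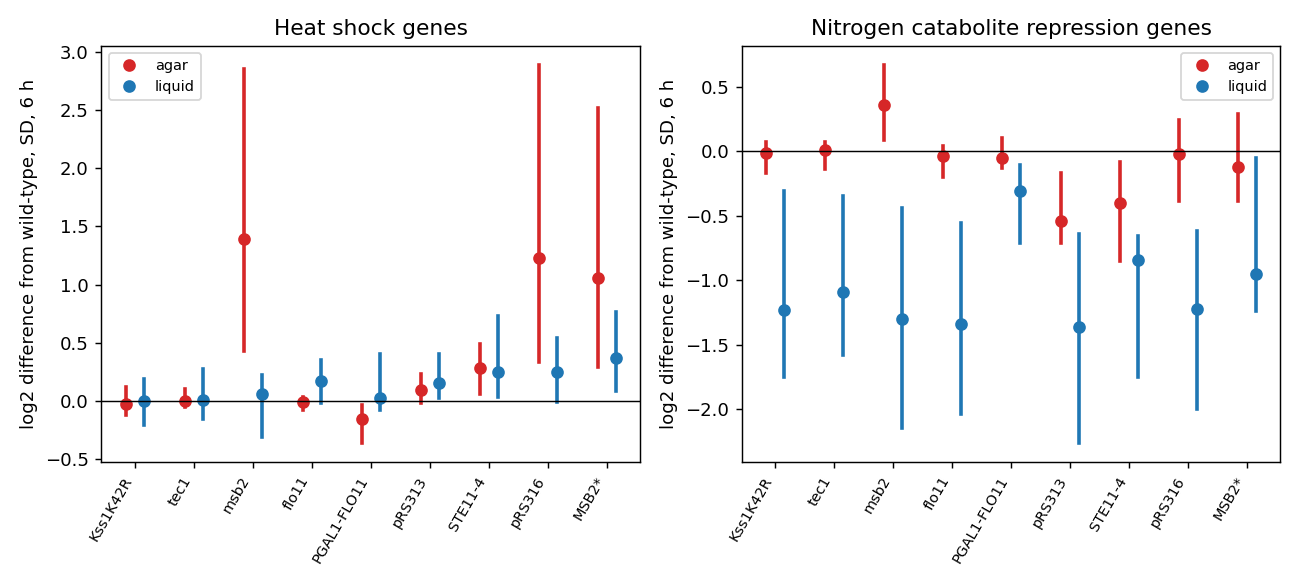
Difference from wild-type in SD at 6 h (log2, y axis) for 22 heat shock genes (left) and 23 nitrogen catabolite repression genes (right), by strain on the x axis. Points are medians over the genes of the list and bars their quartiles, on agar (red) and in liquid (blue). The heat shock medians on agar were 1.39 in msb2, 1.23 in pRS316 and 1.06 in MSB2*.

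The plasmid controls carry no altered allele per the labels and are what STE11-4 and MSB2* are set against. With pRS313, FLO11 rose from 10.05 ± 0.10 to 14.11 ± 0.13, along with 3.13 ± 0.27 for CRC1, 2.98 ± 0.18 for BDS1 and 2.68 ± 0.24 for CIS1, and the falls were -3.33 ± 0.29 for AQY2, -3.02 ± 0.48 for HXT4 and -2.35 ± 0.54 for HSP30. Of iron regulon genes, 14 of 19 measured fell and 5 did not pass (14 fell and 1 rose adjusted over the list alone). With pRS316, FLO11 was already 12.71 ± 0.52 in liquid and read 15.06 ± 0.05 on agar. Its other rises were 4.36 ± 0.34 for BTN2, 3.24 ± 0.46 for HSP42 and 3.19 ± 0.54 for HSP30. Its falls were -3.36 ± 0.30 for MUP1, -2.62 ± 0.18 for EEB1 and -2.61 ± 0.22 for POX1. Of nitrogen catabolite repression genes, 14 of 23 measured rose, 3 fell and 6 did not pass (14 rose and 3 fell adjusted over the list alone). Neither list passed camera with an estimated correlation (adjusted p = 0.555 and 0.626). The counts were 42 up and 89 down with pRS313, and 143 up and 123 down with pRS316.

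STE11-4 and MSB2* were compared with their empty plasmids to see what the altered kinase and mucin alleles change. PGU1, the polygalacturonase gene, rose most on agar: to 11.44 ± 0.47 in STE11-4, at least 39.2-fold above pRS313, and to 13.39 ± 0.13 in MSB2*, against 6.07 ± 0.22 with pRS316, where 2 of 3 arrays were above background. FUS1, needed for cell fusion in mating, SST2, which dampens pheromone signalling, and the cell wall gene TIP1 rose in STE11-4 by 3.06 ± 0.17 for FUS1, 2.27 ± 0.12 for SST2 and 2.57 ± 0.35 for TIP1. In MSB2*, the rises were 3.10 ± 0.35 for TIP1, 2.95 ± 0.25 for DDR48, 2.83 ± 0.17 for FUS1 and 2.81 ± 0.22 for POX1. Of filamentation targets, 7 of 10 measured rose and 3 did not pass (9 adjusted over the list alone) in STE11-4 and 9 of 10 measured rose and 1 did not pass (9 adjusted over the list alone) in MSB2*. Of pheromone-response genes, 11 of 20 measured rose and 9 did not pass (14 adjusted over the list alone) in STE11-4 and 9 of 20 measured rose and 11 did not pass (9 adjusted over the list alone) in MSB2*. In osmotic stress genes, 7 of 12 measured rose and 5 did not pass (7 adjusted over the list alone) in MSB2*. The filamentation count in MSB2* includes MSB2, the gene on the plasmid, without which 8 of 9 rose (camera adjusted p = 3.24e-11 with an estimated correlation). All 5 results passed camera with an estimated correlation (adjusted p = 1.98e-10 to 7.31e-10 in STE11-4 and 1.90e-10 to 0.0148 in MSB2*). Falls were -1.67 ± 0.33 for PRM7 and -1.01 ± 0.24 for TIR3 in STE11-4 and -2.29 ± 0.31 for PHM8, -2.21 ± 0.20 for TAT2 and -1.75 ± 0.20 for FRE7 in MSB2*. STE11-4 had 34 genes higher and 9 lower, MSB2* 73 and 18. The lists shared 24 and 3 genes, against 0.5 and 0.0 for independent lists. The changes correlated at 0.56 across genes, which are not independent replicates, and the comparisons share no arrays.

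In liquid, STE11-4 and MSB2* raised PGU1 and stress genes. PGU1 read 9.83 ± 0.34 in STE11-4 and 11.02 ± 0.16 in MSB2*, against 6.02 ± 0.21 and 5.98 ± 0.20 with the plasmids, where 2 and 1 of 3 arrays were above background. In STE11-4 the log2 change was 4.16 ± 0.54 for YRO2, 3.64 ± 0.54 for HSP30 and 3.17 ± 0.37 for HSP12, and in MSB2* 3.41 ± 0.24 for SPG4, 3.36 ± 0.20 for STL1 and 2.88 ± 0.23 for HXT5, STL1 being the glycerol symporter. Of general stress genes, 17 of 20 measured rose and 3 did not pass (17 adjusted over the list alone) in STE11-4 and 10 of 20 measured rose and 10 did not pass (13 adjusted over the list alone) in MSB2*. In filamentation targets, 7 of 10 measured rose and 3 did not pass (8 adjusted over the list alone) in STE11-4 and 9 of 10 measured rose and 1 did not pass (9 adjusted over the list alone) in MSB2*, or 8 of 9 without MSB2 (adjusted p = 9.67e-08 with an estimated correlation). Osmotic stress genes rose in MSB2* (11 of 12 measured rose and 1 did not pass, 11 adjusted over the list alone), as did gluconeogenesis, glyoxylate and acetate genes (13 of 18 measured rose and 5 did not pass, 14 adjusted over the list alone), while of ergosterol synthesis genes, 13 of 19 measured fell and 6 did not pass (15 adjusted over the list alone). All of these passed camera with an estimated correlation (adjusted p = 4.76e-05 to 0.036 in STE11-4, 3.61e-07 to 0.0123 in MSB2*) except general stress in MSB2* (adjusted p = 0.244). FLO11 read 13.03 ± 0.78 in STE11-4 liquid against 10.05 ± 0.10 with pRS313, and 13.29 ± 0.50 in MSB2* liquid against 12.71 ± 0.52 with pRS316. Liquid counts were 140 higher and 13 lower in STE11-4 (451 and 434 at any size), and 114 and 32 in MSB2*. The 2-fold lists shared 67 and 7 (2.9 and 0.1 if independent). STE11-4 liquid replicate C lay 0.292 log2 from its group. A fit on own arrays called 101 genes in STE11-4 liquid.

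Between agar and liquid, STE11-4 had 36 genes up and 204 down (842 and 892 at any size). Falls included -6.04 ± 0.54 for YRO2, -5.74 ± 0.54 for HSP30 and -3.80 ± 0.26 for TDA6. Rises were 3.03 ± 0.24 for CIS1, 2.27 ± 0.27 for CRC1 and 1.96 ± 0.17 for FUS1. Of its general stress genes, 20 of 20 measured fell (20 adjusted over the list alone), adjusted p = 0.105 with an estimated correlation. In MSB2*, 43 genes rose and 84 fell, with 3.22 ± 0.24 for CIS1, 3.03 ± 0.34 for BTN2 and 2.37 ± 0.19 for PGU1, and falls of -3.15 ± 0.23 for HXT5 and -2.88 ± 0.31 for TKL2. Of its stationary-phase markers, 6 of 10 measured fell and 4 did not pass (7 adjusted over the list alone), a shift that passed camera with an estimated correlation (adjusted p = 0.0074). The agar effect of STE11-4 differed from that of pRS313 for 93 genes, 20 higher and 73 lower, with 2.39 ± 0.24 for FUS1, -4.42 ± 0.76 for YRO2, -3.39 ± 0.76 for HSP30 and -2.91 ± 0.41 for FLO11. That number was 141 without STE11-4 liquid replicate A and 60 without replicate C. For MSB2* against pRS316 it was 39 genes, 19 higher and 20 lower, with 2.57 ± 0.26 for EEB1, -3.06 ± 0.44 for PHM8 and -2.22 ± 0.34 for SPG4. Of the 247 wild-type response genes, 138 passed the same way in STE11-4 and 68 in MSB2*, against 138 and 141 with their plasmids.

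In SD, the arrays labelled PGAL1-FLO11 showed a FLO11 rise on agar of 3.86 ± 0.29, rises of 3.54 ± 0.24 for CIS1, 2.91 ± 0.18 for BDS1 and 2.34 ± 0.19 for SUL1, and falls of -6.82 ± 0.54 for HSP30, -5.35 ± 0.54 for YRO2 and -4.42 ± 0.46 for HSP42. Of cell wall genes, 16 of 22 measured fell and 6 did not pass (16 adjusted over the list alone), and of general stress genes, 13 of 20 measured fell and 7 did not pass (13 adjusted over the list alone). These lists did not pass camera with an estimated correlation (adjusted p = 0.827). There were 97 genes up and 223 down, and 199 of the 247 wild-type response genes passed in the same direction. Against wild-type on SD agar, 4 genes were higher and 31 lower, with -3.45 ± 0.34 for FMP23, -2.80 ± 0.20 for ZTA1, -2.25 ± 0.37 for PIR3 and -2.20 ± 0.20 for PCS60, and 23 passed without wild-type agar replicate C. In SD liquid, 45 were higher and 19 lower, or 36 and 24 after median centring, with 3.45 ± 0.32 for GPM2, 3.07 ± 0.31 for SNO1 and -1.92 ± 0.37 for PIR3. With replicate letters as a block the total was 37. The agar effect differed for 115 genes, 19 higher and 96 lower, or 24 and 50 after quantile normalization, with -4.46 ± 0.48 for FMP23, -4.21 ± 0.46 for GPM2 and 2.02 ± 0.27 for SUL1. That number was 73 without PGAL1-FLO11 liquid replicate B.

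In SG, FLO11 read 15.21 ± 0.03 on agar and 15.19 ± 0.03 in liquid in the arrays labelled PGAL1-FLO11, near the top of the array range, whose 99th percentile had a median of 14.94. Rises on agar were 2.95 ± 0.19 for PGU1, 2.78 ± 0.24 for CIS1 and 2.77 ± 0.27 for PRM5, and falls were -3.79 ± 0.47 for FIT2, -3.58 ± 0.54 for YRO2 and -3.28 ± 0.29 for AQR1. Of nitrogen catabolite repression genes, 17 of 23 measured fell, 1 rose and 5 did not pass (17 fell and 1 rose adjusted over the list alone). This list did not pass camera with an estimated correlation (adjusted p = 0.228). There were 94 genes up and 71 down. Against wild-type on SG agar, the amino acid permease genes DIP5, TAT2 and GAP1 were lower, with -3.27 ± 0.19 for DIP5, -2.44 ± 0.20 for TAT2 and -2.38 ± 0.29 for GAP1, and there were 9 genes higher and 12 lower in all. That total of 21 was 12 without wild-type agar replicate C, without PGAL1-FLO11 agar replicate B or without its replicate C, and 1 with replicate letters as a block. In SG liquid, 494 genes were higher and 472 lower, with 2.74 ± 0.21 for AAH1, 2.60 ± 0.25 for DHR2 and 2.48 ± 0.12 for KRE33, and falls of -4.32 ± 0.26 for GIP2 and -3.86 ± 0.16 for SPG1. DHR2 and KRE33 act in ribosome synthesis. Of ribosome biogenesis genes, 30 of 30 measured rose (30 adjusted over the list alone), of general stress genes, 18 of 20 measured fell and 2 did not pass (18 adjusted over the list alone), and of cytosolic ribosomal protein genes, 124 of 127 measured rose and 3 did not pass (125 adjusted over the list alone). The ribosomal protein list passed camera with an estimated correlation (adjusted p = 0.0489), the other lists did not (adjusted p = 0.405 to 0.46). The agar effect differed from wild-type for 998 genes, 492 higher and 506 lower, with 4.46 ± 0.23 for SPG1, 4.43 ± 0.36 for GIP2, -4.01 ± 0.27 for DIP5 and -2.67 ± 0.22 for SFG1.

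Over the 6 h of growth in SD, wild-type FLO11 went from 11.50 ± 0.66 (n = 6) to 14.81 ± 0.06 on agar, and from 11.97 ± 0.64 to 10.41 ± 0.16 in liquid, log2 changes of 3.31 ± 0.25 and -1.55 ± 0.29 (limma adjusted p = 1.60e-16 and 9.67e-06). On agar, rises included 2.11 ± 0.15 for BAT2 and 1.90 ± 0.28 for PRM7, and falls -2.49 ± 0.26 for STR3 and -2.25 ± 0.26 for MUP1. TCA cycle genes rose on agar (10 of 12 measured rose and 2 did not pass, 10 adjusted over the list alone), at a median of 0.37. Of nitrogen catabolite repression genes, 9 of 23 measured fell, 4 rose and 10 did not pass (11 fell and 5 rose adjusted over the list alone). Of iron regulon genes in liquid, 16 of 19 measured rose and 3 did not pass (16 adjusted over the list alone), and of nitrogen catabolite repression genes, 15 of 23 measured rose, 3 fell and 5 did not pass (16 rose and 3 fell adjusted over the list alone), with 2.96 ± 0.47 for FIT2, 2.41 ± 0.33 for ARN2 and 2.84 ± 0.39 for DAL80. The largest falls in liquid were -4.54 ± 0.32 for GPM2, -4.14 ± 0.34 for EGO4 and -3.64 ± 0.41 for RGI1. None of these lists passed camera with an estimated correlation (adjusted p = 0.0619 to 0.905 on agar and 0.963 to 0.966 in liquid). On agar 36 genes rose and 59 fell. The 0 h agar arrays alone carry fewer decimals, so a difference in their processing and the time point cannot be told apart. In liquid 82 rose and 265 fell, or 135 and 179 after quantile normalization and 155 and 199 after median centring, as the all-gene median moved by -0.116.

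Across the 13 comparisons of agar with liquid, over all strains and nutrients, 16 genes rose and 27 fell in every one. Among those that rose, the lowest and highest log2 changes were 0.76 and 3.77 for the sulfatase gene BDS1 and 0.76 and 3.73 for SFG1. Those that fell in all 13 included HPF1 (-3.13 to -0.95), PST1 (-1.62 to -0.72) and PRY1 (-3.61 to -0.57), which are secreted or cell wall proteins. At 2-fold or more in all 10 SD comparisons, CIS1 rose, and BAP2, HXT5, MUP1, RGS2, YLR154C-H and YPS3 fell. These genes were picked by that count, after their values were seen, and several comparisons share the wild-type strain but no arrays.

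**Figure D4:**
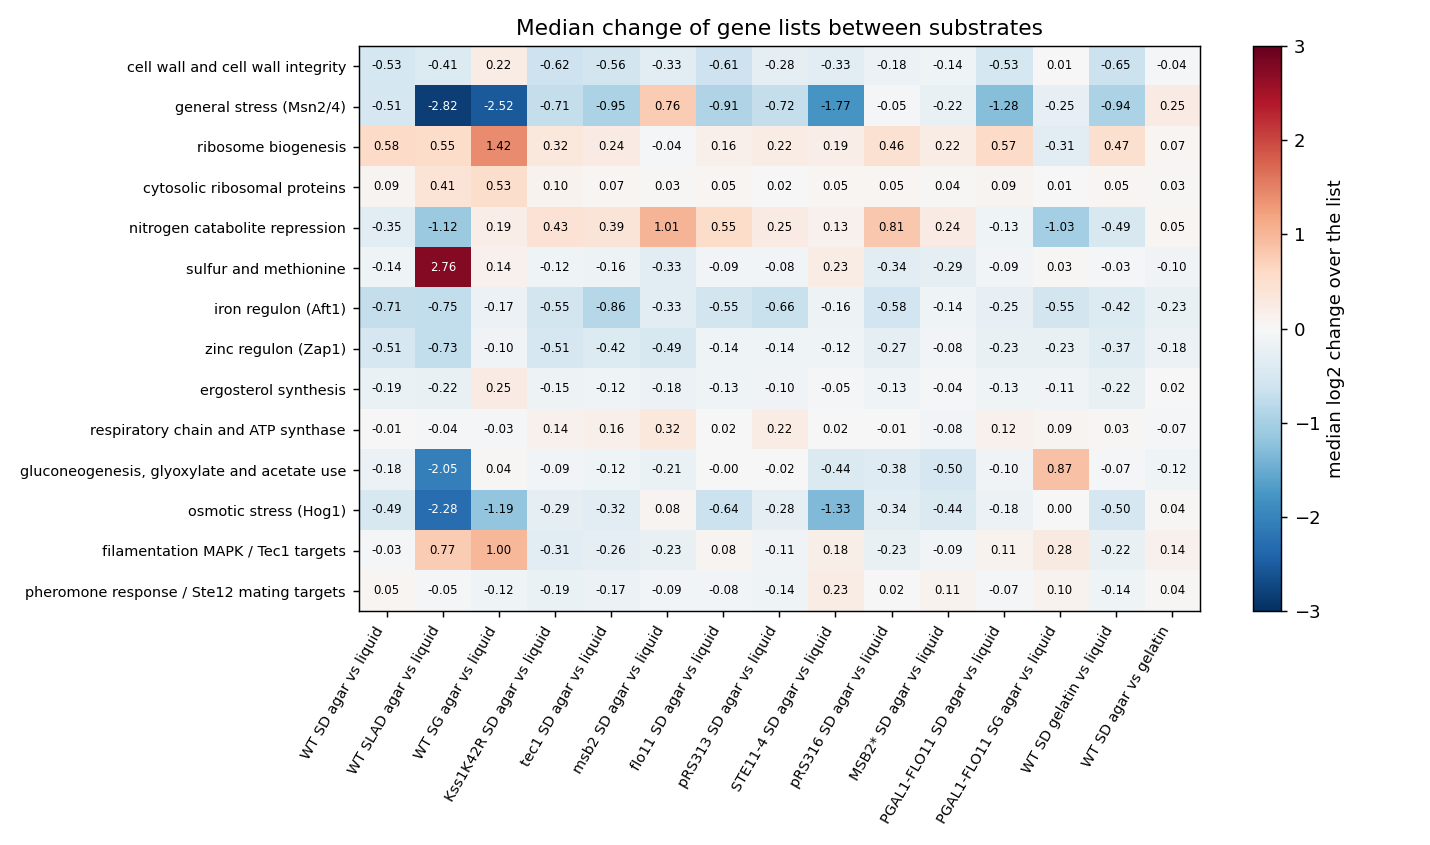
Median log2 change (colour and printed number) of 14 gene lists on the y axis in the 15 substrate comparisons on the x axis. Red is higher on the first-named substrate and blue lower. In sulfur and methionine genes, the median is 2.76 in SLAD and -0.14 in SD.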

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

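The tests weighing the heat shock, nitrogen catabolite repression and SG liquid patterns were chosen only after the results were seen and the counts of other splits of the arrays were planned. Heat shock genes were higher in msb2 than in wild-type on SD agar, by a median of 1.39 log2 over 22 genes. As the only cause, the loss of MSB2 was argued against by pRS316. On SD agar, median pRS316 minus wild-type was 1.23 and msb2 minus pRS316 0.07. A part in msb2 stays open (pRS313 minus wild-type 0.09). A condition shared by the agar cultures or arrays of msb2, pRS316 and MSB2* may explain the pattern.

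Nitrogen catabolite repression genes were lower in Kss1K42R, tec1, msb2 and flo11 than in wild-type in SD liquid, by medians of -1.23, -1.09, -1.30 and -1.34. That each mutation lowers these genes was argued against by the pRS313 strain, against which the lowest of the 4 medians was 0.13. A candidate explanation is that the wild-type SD liquid arrays stand apart from those of the plasmid strains as well as from those of the mutants: the higher of the medians of pRS313 and pRS316 minus wild-type was -1.22. The arrays labelled PGAL1-FLO11 lay closer to wild-type, at -0.31, and a difference in strain background stays open as untested.

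Between the arrays labelled PGAL1-FLO11 and wild-type in SG liquid 966 genes differed. A single deviating array was argued against, since 989 genes were called without wild-type SG liquid replicate C. The wild-type SG liquid cultures may stand apart from the other SG cultures: they were the farthest of the 4 SG groups for 66.5% of all 5449 genes and 93.1% of those called, a share that the choice of genes raises. A part for more FLO11 message in the arrays labelled PGAL1-FLO11 cannot be judged, since their FLO11 difference of 0.46 lies near the top of the array range.

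The effect of agar differed between groups in 10 comparisons. Of 100 splits, those with as many genes as the real one, itself included, are given with the highest other count. Excluded means only a share under 0.05, unadjusted for 10 tests. Chance can be excluded for the gene counts 71 between Kss1K42R and wild-type (4 of 100, highest other 183), 107 between tec1 and wild-type (3 of 100, highest other 177), 296 between msb2 and wild-type (3 of 100, highest other 402), 115 between PGAL1-FLO11 and wild-type in SD (1 of 100, highest other 111), 998 between PGAL1-FLO11 and wild-type in SG (4 of 100, highest other 1079) and 955 between SLAD and SD in wild-type (2 of 100, highest other 956). It cannot be excluded for 103 between flo11 and wild-type (7 of 100, highest other 167), 93 between STE11-4 and pRS313 (11 of 100, highest other 172), 39 between MSB2* and pRS316 (17 of 100, highest other 371) and 682 between SG and SD in wild-type (10 of 100, highest other 2118). Some splits exchange strains or nutrients within 1 substrate, measuring the summed strain difference, so the shares cannot decide on chance. Counts several times the real one (MSB2*, SG) point to such structure.

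For wild-type SD agar at 6 h against 0 h, 1 of 84 splits, the real one, gave 95 genes, a share under 0.05. The highest other gave 35. The other 36 comparisons have 10 splits each, too few for a share under 0.05. The counts, with the highest other in brackets and / for against, were 1310 (11) for WT SLAD agar/liquid, 857 (65) for WT SG agar/liquid, 292 (2) for tec1 SD agar/liquid, 251 (50) for msb2 SD agar/liquid, 195 (1) for flo11 SD agar/liquid, 240 (9) for STE11-4 SD agar/liquid, 266 (1) for pRS316 SD agar/liquid, 320 (23) for PGAL1-FLO11 SD agar/liquid, 165 (10) for PGAL1-FLO11 SG agar/liquid, 212 (96) for WT SD gelatin/liquid, 30 (6) for Kss1K42R/WT SD agar, 36 (1) for tec1/WT SD agar, 163 (87) for msb2/WT SD agar, 19 (1) for flo11/WT SD agar, 43 (2) for STE11-4/pRS313 SD agar, 91 (4) for MSB2*/pRS316 SD agar, 153 (5) for STE11-4/pRS313 SD liquid, 64 (2) for PGAL1-FLO11/WT SD liquid, 966 (150) for PGAL1-FLO11/WT SG liquid, 910 (19) for WT SLAD/SD liquid, 671 (105) for WT SG/SD agar, 1606 (173) for WT SG/SD liquid and 347 (1) for WT SD liquid 6 h/0 h. For SD agar against gelatin in wild-type the real count was 48, 4 of the 10 splits gave as many and the highest other gave 97. In 12 comparisons limma called 0 genes in every other split, where 5 to 42 genes passed an unadjusted p under 0.05 at 2-fold in the split with most. The real counts there were 247 for WT SD agar/liquid, 257 for Kss1K42R SD agar/liquid, 131 for pRS313 SD agar/liquid, 127 for MSB2* SD agar/liquid, 35 for PGAL1-FLO11/WT SD agar, 21 for PGAL1-FLO11/WT SG agar, 73 for Kss1K42R/WT SD liquid, 82 for tec1/WT SD liquid, 83 for msb2/WT SD liquid, 91 for flo11/WT SD liquid, 146 for MSB2*/pRS316 SD liquid and 24 for WT SLAD/SD agar. Apart from agar against gelatin, 1 of the 10 splits, the real one, was as large.

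Replicate D of wild-type SD agar at 0 h lay apart from the other 5 arrays in the mean of 4 gene lists: its gap to the nearest array was 0.640 of the range for nitrogen catabolite repression, 0.632 for Gcn4 amino acid biosynthesis, 0.635 for hexose transporters and 0.661 for G1/S genes. These are 4 of 49 values checked, and chance alone marks about 1 in 20. The probe set RPTR-Sc-AJ002682-1_s_at, which names no gene and entered no comparison, had a mean of 15.24 ± 0.06 in the 18 arrays of tec1, msb2 and flo11 and of 5.12 ± 0.37 in the 72 others, where the highest value was 7.45. The probe set RPTR-Sc-AJ002682-2_s_at had a mean of 9.12 ± 0.45 in the 24 arrays of the strains with pRS313 or pRS316 plasmids and of 5.95 ± 0.24 in the 66 others.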

How the results depend on the processing

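The control pRS313 and the filamentation list without an altered gene were chosen after seeing the data and all other alternatives were planned. Here / stands for against, and the genes that rose are in brackets where the balance turned. Averaging probe sets and median centring left all 47 gene counts within 1.5 times the reported ones, quantile normalization 45, a fit on own arrays 43, a replicate block 43, leaving out dim genes 15. Which of the rises and falls were more numerous turned in 13 of 47 comparisons without dim genes, 9 without a fold threshold, 7 after quantile normalization, 6 after median centring, 1 each with a fit on own arrays and with the block, 8 when 1 array was left out, 2 of 6 against pRS316 and 3 of 15 against pRS313. Named genes and list medians reversed only against another control strain. The 629 named gene results had 8287 values under alternatives, of which 7808 kept direction and call, 405 kept direction but not the call and 74 reversed. In 55 results the call was lost when at least 1 array was left out. Signal over background limits the 232 genes with a mean under the background limit. Sets of arrays were not used as a block. The filamentation list median in tec1/WT SD agar was -0.32 without TEC1, and that list still passed camera.

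Without a fold threshold every count rose, by construction: 2829 (1678 up) for WT SD agar/liquid, 3971 (2141 up) for WT SLAD agar/liquid, 3522 for WT SG agar/liquid, 2365 for Kss1K42R SD agar/liquid, 2258 for tec1 SD agar/liquid, 2264 (1077 up) for msb2 SD agar/liquid, 1715 for flo11 SD agar/liquid, 1088 for pRS313 SD agar/liquid, 1734 for STE11-4 SD agar/liquid, 2297 (1020 up) for pRS316 SD agar/liquid, 971 for MSB2* SD agar/liquid, 2315 for PGAL1-FLO11 SD agar/liquid, 1187 for PGAL1-FLO11 SG agar/liquid, 2025 for WT SD gelatin/liquid, 678 for WT SD agar/gelatin, 317 for Kss1K42R/WT SD agar, 364 for tec1/WT SD agar, 1723 for msb2/WT SD agar, 57 for flo11/WT SD agar, 200 for STE11-4/pRS313 SD agar, 522 for MSB2*/pRS316 SD agar, 78 for PGAL1-FLO11/WT SD agar, 100 (65 up) for PGAL1-FLO11/WT SG agar, 1243 for Kss1K42R/WT SD liquid, 1360 for tec1/WT SD liquid, 1506 (1086 up) for msb2/WT SD liquid, 2552 for flo11/WT SD liquid, 885 for STE11-4/pRS313 SD liquid, 1108 (552 up) for MSB2*/pRS316 SD liquid, 1217 for PGAL1-FLO11/WT SD liquid, 3550 for PGAL1-FLO11/WT SG liquid, 365 for Kss1K42R/WT SD agar effect, 571 for tec1/WT SD agar effect, 1260 (442 up) for msb2/WT SD agar effect, 953 for flo11/WT SD agar effect, 248 for STE11-4/pRS313 SD agar effect, 94 (59 up) for MSB2*/pRS316 SD agar effect, 546 for PGAL1-FLO11/WT SD agar effect, 2944 for PGAL1-FLO11/WT SG agar effect, 2796 for WT SLAD/SD agar effect, 2597 for WT SG/SD agar effect, 97 for WT SLAD/SD agar, 3456 for WT SLAD/SD liquid, 3406 for WT SG/SD agar, 4252 for WT SG/SD liquid, 1205 for WT SD agar 6 h/0 h and 3040 for WT SD liquid 6 h/0 h. Leaving out dim genes, with fewer genes tested, gave 184 for tec1 SD agar/liquid, 128 for flo11 SD agar/liquid, 82 for pRS313 SD agar/liquid, 139 for STE11-4 SD agar/liquid, 177 for pRS316 SD agar/liquid, 68 for MSB2* SD agar/liquid, 212 for PGAL1-FLO11 SD agar/liquid, 96 for PGAL1-FLO11 SG agar/liquid, 13 for Kss1K42R/WT SD agar, 17 for tec1/WT SD agar, 97 for msb2/WT SD agar, 8 for flo11/WT SD agar, 14 for STE11-4/pRS313 SD agar, 41 for MSB2*/pRS316 SD agar, 16 for PGAL1-FLO11/WT SD agar, 12 for PGAL1-FLO11/WT SG agar, 35 (13 up) for Kss1K42R/WT SD liquid, 47 (23 up) for tec1/WT SD liquid, 42 for msb2/WT SD liquid, 48 (18 up) for flo11/WT SD liquid, 82 for STE11-4/pRS313 SD liquid, 73 for MSB2*/pRS316 SD liquid, 36 for PGAL1-FLO11/WT SD liquid, 31 (18 up) for Kss1K42R/WT SD agar effect, 43 for tec1/WT SD agar effect, 57 (31 up) for flo11/WT SD agar effect, 53 for STE11-4/pRS313 SD agar effect, 15 (11 up) for MSB2*/pRS316 SD agar effect, 56 for PGAL1-FLO11/WT SD agar effect, 451 (255 up) for WT SG/SD agar effect, 396 for WT SG/SD agar and 190 for WT SD liquid 6 h/0 h. A fit on own arrays gave 88 for WT SD gelatin/liquid, 0 for WT SD agar/gelatin by limma (46 at an unadjusted p under 0.05), 93 for msb2/WT SD agar and 101 for STE11-4/pRS313 SD liquid. A replicate block gave 9 for WT SD gelatin/liquid, 0 for WT SD agar/gelatin by limma (45 unadjusted), 1 for PGAL1-FLO11/WT SG agar and 37 for PGAL1-FLO11/WT SD liquid. Quantile normalization gave 67 for tec1/WT SD agar effect and 74 for PGAL1-FLO11/WT SD agar effect. The cause was not tested for the last 3 settings.

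With pRS316 as the control in place of wild-type, the counts were 98 (19 up) for msb2/WT SD agar, 256 for flo11/WT SD agar, 161 for msb2/WT SD liquid, 106 for msb2/WT SD agar effect and 281 for flo11/WT SD agar effect. Reversed log2 differences were -0.49 for HSP42, -0.31 for BTN2, 2.24 for HXT1 and -0.62 for general stress median in msb2/WT SD agar, with 0.14 for PRM1 in flo11/WT SD agar, with -0.54 for SNO1, -0.45 for SNZ1, -0.62 for GPM2, -0.49 for IZH4, -0.57 for FMP23, 0.06 for DAL5, 0.09 for DAL7 and -0.60 for TEC1 in msb2/WT SD liquid. Others were -0.41 for GPM2, -0.87 for SNO1, -0.43 for SNZ1, 0.03 for DAL5, 0.15 for DAL7, -0.02 for KSS1 and -0.47 for TEC1 in flo11/WT SD liquid, with -0.08 for BTN2, -2.47 for HSP30, 0.21 for RFU1 and 0.06 for KSS1 in msb2/WT SD agar effect, with -0.63 for DAL80 and 1.67 for FMP23 in flo11/WT SD agar effect. The cause was not tested.

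With pRS313 as the control, the counts were 53 for Kss1K42R/WT SD agar, 39 (20 up) for Kss1K42R/WT SD agar effect, 69 for tec1/WT SD agar, 56 for tec1/WT SD agar effect, 50 for flo11/WT SD agar, 20 (7 up) for flo11/WT SD liquid, 13 (10 up) for flo11/WT SD agar effect and 65 for PGAL1-FLO11/WT SD agar effect. Reversed log2 differences were -0.77 for YAT1, -0.73 for SSP1, -1.05 for CRC1 and -0.32 for MET28 in Kss1K42R/WT SD agar, with -0.82 for SNO1, 0.40 for DAL80, 0.49 for DAL7, 0.94 for DAL5, 0.97 for DAL4, -0.15 for KSS1 and 0.40 for nitrogen catabolite repression median in Kss1K42R/WT SD liquid, with -0.03 for DAL4 and 0.03 for GPM2 in Kss1K42R/WT SD agar effect. Others were -0.76 for YAT1 and -1.10 for CRC1 in tec1/WT SD agar, with 0.61 for DAL80, 0.84 for DAL7, 1.67 for DAL5 and 0.48 for nitrogen catabolite repression median in tec1/WT SD liquid, with -0.67 for DAL5 in tec1/WT SD agar effect. Further reversals were -0.90 for SNO1, -0.70 for SNZ1, -1.09 for GPM2, -1.29 for FMP23, 0.05 for DAL80, 0.46 for DAL5, 0.35 for DAL7, -0.39 for TEC1 and 0.16 for nitrogen catabolite repression median in msb2/WT SD liquid, with -0.26 for SEO1 and -0.58 for COS12 in flo11/WT SD agar, with -0.88 for GPM2, -1.24 for SNO1, -0.68 for SNZ1, -0.22 for NGL3, 0.27 for DAL80, 0.44 for DAL5, 0.41 for DAL7, 0.27 for DAL4, -0.09 for KSS1, -0.27 for TEC1 and 0.13 for nitrogen catabolite repression median in flo11/WT SD liquid. There were also 0.13 for GPM2 and 1.83 for FMP23 in flo11/WT SD agar effect, with -0.72 for YAT1, -0.52 for COS12, -0.39 for SEO1 and 0.05 for HSP30 in PGAL1-FLO11/WT SD agar, with -0.16 for SNZ1, 0.10 for PUT4 and 1.90 for DAL80 in PGAL1-FLO11/WT SD liquid. Reversed too were -0.14 for VBA2 and -1.35 for DAL80 in PGAL1-FLO11/WT SD agar effect. The cause was not tested.

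When arrays were left out in turn, the counts that moved ranged from 44 to 131 for WT SD agar/gelatin, 101 to 276 for msb2/WT SD agar, 23 to 40 for PGAL1-FLO11/WT SD agar, 12 to 20 for PGAL1-FLO11/WT SG agar, 66 to 154 for flo11/WT SD liquid, 193 to 450 for msb2/WT SD agar effect, 55 to 198 for flo11/WT SD agar effect, 60 to 141 for STE11-4/pRS313 SD agar effect and 73 to 129 for PGAL1-FLO11/WT SD agar effect.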

Other observations

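Several gene lists moved in ways the comparisons above leave out. In STE11-4 liquid against pRS313, of the stationary-phase markers, 6 of 10 measured rose and 4 did not pass (6 adjusted over the list alone), with 2.92 ± 0.24 for SPG4, 2.12 ± 0.31 for GRE1 and 1.43 ± 0.29 for FMP45, and in MSB2* liquid against pRS316, 6 of 10 measured rose and 4 did not pass (6 adjusted over the list alone). Both shifts passed camera with an estimated correlation (adjusted p = 0.0019 and 0.0092). Of osmotic stress genes in STE11-4 liquid, 7 of 12 measured rose and 5 did not pass (10 adjusted over the list alone), with 3.17 ± 0.37 for HSP12 and 2.12 ± 0.31 for GRE1 (adjusted p = 0.0011 with an estimated correlation). Of a-cell markers there, 4 of 7 measured rose and 3 did not pass (4 adjusted over the list alone), adjusted p = 0.0362 with an estimated correlation.

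Between SG and SD in wild-type liquid, of low-oxygen genes, 11 of 16 measured fell, 2 rose and 3 did not pass (11 fell and 2 rose adjusted over the list alone), of ergosterol synthesis genes, 17 of 19 measured fell, 1 rose and 1 did not pass (17 fell and 1 rose adjusted over the list alone), and of TCA cycle genes, 12 of 12 measured rose (12 adjusted over the list alone). Their adjusted p with an estimated correlation were 0.603, 0.0209 and 0.185 in that order.

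The tests of 1 hypothesis, that an altered pathway allele alone brings about part of the wild-type agar response in liquid, were chosen only after the results were seen. Over the 247 genes of the wild-type SD agar response, the slope of the STE11-4 change in liquid on the wild-type change was -0.09. This cannot exclude a part: of 90 genes that passed, 34 went the same way and 56 the opposite. For MSB2* in liquid the slope was 0.15, with 60 of 81 genes the same way, so that MSB2* may bring about a small part of it.

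Of 3470 unnamed probe sets other than controls and reporters, 316 were above background, and 4 of these rose and 13 fell at least 2-fold between wild-type SD agar and liquid.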
